A study of Mus musculus with 7 samples.

How the data were processed

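ATAC-seq was performed on epithelial cells purified from mouse pancreas before and after caerulein-induced inflammation, per the labels' protocols: nuclei from lysed cells were treated with Tn5 transposase and the libraries were sequenced on Illumina instruments. The series lists 7 samples. Peak lists of 4 of them were used, 1 each from untreated epithelium and from days 1, 7 and 28 after caerulein; the 3 samples of DCLK1-positive cells were not analysed here. Groups were taken from the sample titles.

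The submitters' processing notes name cutadapt, Bowtie2 2.2.6, SAMtools, MACS2 2.1.0.20150731 and deepTools and the genome build GRCm38 (mm10). The role and options of each tool, read filters, any shift of reads to the transposase cut site and any removal of problem regions are not given in the sources used here. The files used are peak lists in the narrowPeak layout, 1 for each of the 4 samples analysed. The authors' fold enrichment at the summit is a ratio of pileup to background. The authors' −log10 p and −log10 q columns measure the same enrichment, and their score column equals 10 times the −log10 q in 100% of the rows of each list. The remaining column used is the deposited offset of the summit. The lowest −log10 q in the lists was 1.99, 1.89, 2.31 and 1.91 for untreated, day 1, day 7 and day 28, and the narrowest peak was 146 bp in each.

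Depth was recovered from the authors' fold enrichment and −log10 p. With fold as pileup plus 1 over background plus 1 and p as a Poisson upper tail, a single background per list made 100% of the pileups whole within 0.05 and matched 100% of the p-values. The backgrounds were 5.07, 5.35, 2.72 and 2.52, or 2.01, 2.12, 1.08 and 1 relative to day 28, and the lowest pileups in the lists were 14, 14, 10 and 9. A region in the untreated list therefore needed a fold of 2.47, and in the lists of days 1, 7 and 28 a fold of 2.36, 2.95 and 2.84. These differences, and the lower enrichment of the untreated library, can make a region appear gained without any change in the chromatin, and for that reason simulated unchanged libraries stand beside the counts.

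Regions were the distinct intervals on the 19 autosomes and X; no interval occurred more than once. A region was gained when it overlapped no untreated peak by at least 1 bp and lost when an untreated region overlapped no peak of the later list. The counts were checked with bedtools 2.31.1, which gave the same 86230 gained regions at day 1. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Merged regions of the 4 lists were scored present or absent in each. For unchanged libraries, each merged region was given a single accessibility, scaled by each library's median enrichment in the regions that all lists share, and Poisson pileups were drawn at each library's background and passed through its floors, 20 times under each of 3 assumptions on the level in lists that lacked the region (background, the floor and halfway between). This was done with all 4 libraries and for each pair with the untreated library. The accessibility was the mean over the observed lists drawn, so a real gain or loss entered it as well. With 1 library per group no p-value was computed.

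Gene positions came from a RefSeq table of GRCm38.p6, the build of the files, which gives gene spans without strand or exons. The planned link to transcription start sites was therefore replaced: each summit was linked to the nearest protein-coding gene span within 50 kb, and promoters were replaced by the 1 kb around either annotated gene end. Exons and introns could not be separated. Motif content and GC content, also planned, need a genome sequence and were not computed. Before the data were examined, 16 gene lists with 290 genes were written down; 289 matched the table, Ctrc did not, and no gene was in more than 1 list. The lists covered acinar digestive enzymes, acinar transcription factors, ductal and metaplasia, immediate-early and AP-1, EGFR-MAPK, inflammatory and NF-kB, unfolded protein response, cell cycle, tuft cell, endocrine, leukocyte, fibroblast and stellate, endothelial, erythroid, ubiquitous and skeletal muscle genes. Each list's total of gained and of lost regions was placed among 10000 random lists of the same size, matched gene by gene on the number of untreated regions and on the length of the genomic territory in 5 bins. A percentile describes these libraries and is not a p-value. A list of 15 stromal transcription factor genes was added later, before its own result was seen.

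Named regions followed a rule fixed before the data were examined: per comparison the 10 gained regions with the highest fold in the later list and the 10 lost regions with the highest fold in the untreated list that had a gene within 50 kb, and the 10 strongest day 28 regions absent from the untreated list and present at each later time. From each list up to 4 genes with the most gained and up to 4 with the most lost regions could be named, with genes that gained or lost a region at a gene end. Some genes that this rule names are not reported here. The 2 mapped loci are the digestive enzyme gene with the most lost and the AP-1 list gene with the most gained regions at day 1.

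The scripts were tested on simulated data. For day 1 against untreated, 85.0% of 200 regions planted with a 2-fold gain, 90.5% with a 4-fold gain and 85.0% with an 8-fold gain among 223972 merged regions were called gained. The planted regions were drawn only where the untreated signal was expected below that list's floor. No region without a planted gain was run, and the higher day 1 enrichment alone could have passed some. These rates therefore do not measure how well a gain is detected. A planted list of 20 genes reached percentile 99.99, and 2 of 100 unchanged lists lay outside the central 95%. The alternatives tried were a −log10 q of at least 5, a reciprocal overlap of 50%, lists of equal length, a margin between presence and absence, all chromosomes, a width of at least 200 bp and links within 10 kb. After the data had been seen, a fold of at least 3, thinning to the day 28 depth, a common enrichment floor and, for the regions absent from the untreated list alone, a day 28 fold of at least 5 were added. The common floor kept regions whose fold minus 1, divided by its median in shared regions, passed the same value in each list, which meant folds of at least 2.47, 4.31, 4.00 and 3.28. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.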

Results

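Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in epithelial cells purified from the pancreas of C57BL/6J mice. The mice were untreated or had been given caerulein, a cholecystokinin analogue that provokes a transient acute pancreatitis, and were examined at days 1, 7 and 28. Each of these 4 groups was represented by 1 peak list from 1 library, so no difference given here has a replicate check, and every value compares libraries. A further 3 libraries, from DCLK1-positive epithelial cells, were not analysed here. The title of the series names a lasting epithelial memory of resolved inflammation, and the comparisons asked which accessible regions appeared or disappeared during the injury and which of them were still altered at day 28.

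On chromosomes 1 to 19 and X the lists held 140286 regions in untreated epithelium, 164684 at day 1, 145337 at day 7 and 130149 at day 28. They covered 70.3, 97.3, 76.7 and 70.9 Mb, with median widths of 306, 375, 340 and 337 bp. Read totals were not given in the sources used here. The background pileup recovered from the peak caller's fields, which follows depth, was 5.07 in the untreated library, 5.35 at day 1, 2.72 at day 7 and 2.52 at day 28. The libraries also differed in how far peaks stood above that background. In the regions that all 4 lists held, the median of fold enrichment minus 1 was 7.40 in the untreated library, 16.6 at day 1, 15.1 at day 7 and 11.5 at day 28. The untreated library was therefore the least enriched while being deeper than those of days 7 and 28. All fold enrichments are the authors' own values. They rank and filter peaks within a list, and between lists they serve only to gauge and scale each library's enrichment.

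At day 1 most untreated regions at digestive enzyme and acinar transcription factor genes had no peak. Whether the single day 1 preparation held a lower share of acinar cells was not tested for these losses. Of the 281 untreated regions at 23 digestive enzyme genes, 241 had no day 1 peak, and only 11 new regions had appeared; among 10000 matched random gene lists these totals lay at percentiles 100 and 0. The pancreatic lipase gene Pnlip had lost 24 of 30 regions, its relative Pnliprp1 22 of 23 and the zymogen granule protein gene Gp2 21 of 21. A region within 1 kb of an annotated gene end was lost at 19 of the 23 genes, among them Cpa1, Cel, Cela1 and Prss2, and gained at 0. The acinar transcription factor genes had lost 201 of 324 regions (percentile 99.3) and gained 88 (percentile 17.8). Nr5a2 had lost 36 of 47 regions, Gata4 35 of 44 and Ptf1a, which encodes the factor that drives enzyme gene transcription, 14 of 17. Regions near gene ends were lost at 7 of these 12 genes, among them Bhlha15, Nr0b2, Nr5a2, Ptf1a, Rbpjl and Xbp1. Foxp1 differed from the rest of its list, with 69 regions gained and 59 of 110 lost. Unfolded protein response genes, whose products serve secretory cells, had lost 89 of 153 regions (percentile 95.1) and gained 33 (percentile 3.34), and 37 of the lost regions lay at Sel1l.

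New regions at day 1 were frequent at inflammatory genes and at genes of fibroblasts. The inflammatory and NF-kB list gained 174 regions against 265 in the untreated list (percentile 99.7) and lost 61 (percentile 0.745). Its leading members were Il33 with 22 gained regions, Tnfaip3 with 20, Osmr, the oncostatin M receptor gene, with 15, and Il6 with 13. Gene ends gained a region at 10 of the 28 genes, including Ccl2, Cxcl2, Cxcl5 and Il6. The fibroblast and stellate list, included to follow another cell type of the pancreas, gained 177 regions against 140 in the untreated list (percentile 99.9) and lost 9 (percentile 0). Col1a2 gained 27 regions, Prrx1 22, Twist2 20 and Dcn 19, and 9 of the 16 genes gained a region at a gene end. Tuft cell genes gained 104 regions (percentile 97.45), of which 50 lay at Dclk1, a marker of these chemosensory cells, and lost 43 of 117.

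Immediate-early and AP-1 genes lost few regions at day 1, 89 of 344 (percentile 0.87), while their 198 gained regions lay at percentile 89.7, which ran from 89.7 to 98.8 over the settings, the highest with links within 10 kb. Runx1 gained 42 regions and Runx2 34, and both are in the list although they encode RUNX and not AP-1 factors. Among the Fos and Jun genes, Fosl2 gained 18 regions, Fos 13, Jun 8, Fosl1 4, Junb 1, Jund 1 and Fosb 0. Fos also lost 12 of 33. The ductal and metaplasia list had regions of both kinds, and in the main setting neither total left the central range of its random lists. It gained 170 regions (percentile 85.5), of which 76 lay at Cd44, 14 at Anxa1, 13 at Vim and 10 at Spp1, and it lost 122 of 266 (percentile 86.6), of which 14 lay at the duct keratin gene Krt19, 12 at Epcam, 11 at Clu and 10 at Krt18. EGFR-MAPK genes gained 184 regions (percentile 49.1) and lost 121 of 388 (percentile 7.82), with 34 gained at Spred1, 28 at Egfr and 20 lost at Tgfa. Neither total of the cell cycle list, 29 gained and 21 of 74 lost, left the central range of the random lists (percentiles 19.9 and 20.5). Among markers of other cells, leukocyte genes gained 30 and lost 15 of 41 regions (percentiles 39.7 and 59.8), endothelial genes gained 68 and lost 81 of 176 (percentiles 12.1 and 79.5), endocrine genes gained 39 and lost 22 of 76 (percentiles 17.4 and 16.2) and erythroid genes gained 23 and lost 8 of 39 (percentiles 44.8 and 11.8). Ubiquitous genes gained 38 and lost 22 of 78 (percentiles 62.4 and 28.4). Skeletal muscle genes, with only 17 untreated regions, gained 22 and lost 10 (percentiles 99.4 and 97.8).

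The strongest gained region of the day 1 list lay inside Glis1, at chromosome 4, 107602201 to 107603803 on GRCm38, with a fold enrichment of 81.3. The next were inside Gpalpp1 (76.7 fold), 38713 bp from Usp47 (76.3 fold), inside Zdhhc16 (74.4 fold) and inside Kcnab1 (73.3 fold). Fyco1, Tanc1, Mib1, Gata6 and a further region near Usp47 completed the 10 regions, the region near Gata6 lying 36419 bp from the gene at chromosome 18, 11015422 to 11016388. All 10 were present at day 7 and 5 at day 28. The strongest lost region lay inside Marchf10, at chromosome 11, 105374634 to 105376467, with a fold enrichment of 75.0 in the untreated list. It was followed by regions inside Prkcb (73.3 fold), Cracdl (68.9 fold) and Dpp9 (68.9 fold), and then by regions at Lcmt1, Upp2, Kctd2, Larp1, Hemk1 and the lipoprotein lipase gene Lpl. All 10 were again present at days 7 and 28.

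In total 86230 day 1 regions, 52.4% of the list (exact binomial 95% interval 52.1 to 52.6), had no untreated peak, and 52526 untreated regions, 37.4% (37.2 to 37.7), had no day 1 peak. Intervals cover counting error only. A common enrichment floor for all lists, an alternative chosen after seeing the data, removed no untreated region and left 110780 at day 1. By this construction day 1 gains could only fall and losses only rise. The gained regions numbered 46643 and the lost regions 63089, so the balance between them turned with the scaling. It also turned from more gained to more lost regions at EGFR-MAPK genes (95 gained and 153 lost), ductal and metaplasia genes (84 and 150), cell cycle genes (16 and 28), endocrine genes (4 and 27), leukocyte genes (17 and 20) and ubiquitous genes (17 and 27), and AP-1 genes came to 110 and 109. Simulated libraries in which no region changed, drawn at the recovered depths and enrichments, gave between 44930 and 59603 gained and at most 2114 lost regions when day 1 and untreated were drawn as a pair. Drawn with all 4 libraries, they gave 54837 to 82290 gained and at most 2389 lost regions, against 82977 and 47630 observed on the merged regions.

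**Figure D1:**
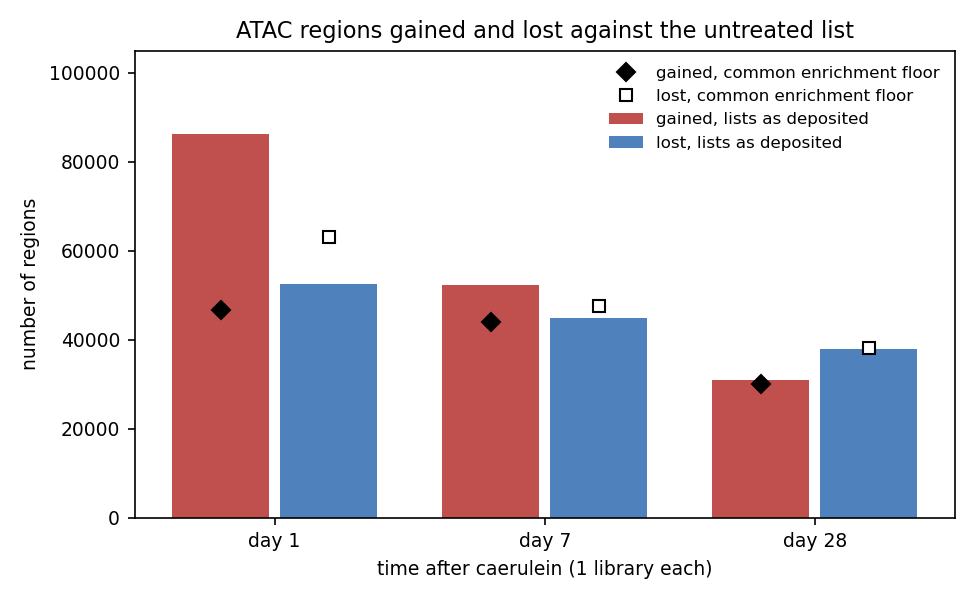
Number of ATAC-seq regions gained and lost against the untreated list at days 1, 7 and 28, with 1 library per time. Bars show the deposited lists, in which 86230 regions were gained at day 1 and 30910 at day 28; diamonds and squares show gained and lost regions under a common enrichment floor, where day 1 had 46643 gained and 63089 lost.

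At day 7 the digestive enzyme genes were still depleted of accessible regions, and the gained regions of inflammatory, AP-1 and fibroblast genes lay above the central range of their random lists. Digestive enzyme genes lacked 190 of 281 regions and had gained 11 (percentiles 100 and 0), and 18 of the 23 had lost a region at a gene end. Gp2 lacked 20 regions, Pnlip 20 and Pnliprp1 20. Acinar transcription factor genes had lost 137 of 324 regions (percentile 94.4) and gained 59 (percentile 22.8). Near gene ends, only Nr0b2 and Ptf1a of this list had lost a region, against 7 genes at day 1. The inflammatory and NF-kB list had gained 147 regions (percentile 100) and lost 54 (percentile 0.405), with 18 gained at Il33, 17 at Il6, 17 at Tnfaip3 and 13 at Ccl2. Immediate-early and AP-1 genes had gained 176 (percentile 99.97) and lost 71 (percentile 0.15), with 36 gained at Runx1, 25 at Fosl2, 17 at Runx2 and 14 at Klf6. Fibroblast and stellate genes had gained 114 and lost 9 (percentiles 100 and 0). The ductal and metaplasia list had gained 119 and lost 79 (percentiles 96.3 and 19.2), with 26 gained at Cd44 and 22 at Anxa1, and the tuft cell list 66 and 36 (percentiles 97.54 and 52.6).

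Unfolded protein response genes at day 7 had gained 29 and lost 75 regions (percentiles 19.6 and 95.2), EGFR-MAPK genes 110 and 116 (percentiles 39.6 and 19.8) and cell cycle genes 26 and 16 (percentiles 65.5 and 10.6). Leukocyte genes had gained 19 and lost 15 (percentiles 47.1 and 80.7), endothelial genes 63 and 70 (percentiles 65.0 and 81.7), endocrine genes 26 and 21 (percentiles 26.5 and 26.8) and erythroid genes 11 and 8 (percentiles 29.8 and 11.8). Ubiquitous genes had gained 44 and lost 15 (percentiles 98.6 and 9.32), with 30 of the gained regions at Ywhaz. Skeletal muscle genes had gained 11 and lost 6 (percentiles 96.1 and 76.6).

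The highest-ranked gained regions of day 7 lay near Mib1 (43.2 fold, 32485 bp from the gene) and Gata6 (34.9 fold) and inside Kcnab1 (33.6 fold), Atp11a (32.2 fold), Tbc1d31 (32.0 fold) and Me1 (32.0 fold), followed by regions at Col6a3, Sema4f, St7 and Fgf23. All 10 were also in the day 1 list and 9 were in the day 28 list. The leading lost regions lay inside Slc16a7 (36.9 fold in the untreated list), near Sh3tc2 (34.1 fold) and inside Shisal1 (33.8 fold), followed by Wsb1, Tbccd1, Gp2, Cytip, Il12rb1, Stard3 and Rad50, and all 10 were present at day 28. Overall counts were 52272 gained regions, 35.97% of the list (35.7 to 36.2), and 44918 lost, 32.0% of the untreated regions (31.8 to 32.3). The common enrichment floor gave 44093 and 47598. Unchanged simulated libraries gave at most 28214 gained and 10959 lost when drawn as a pair. Drawn with all 4 libraries, they gave 30388 to 55290 gained and at most 10235 lost, against 41964 and 39584 observed on the merged regions. The gains lay above every pair draw but within the range of the draws with all 4 libraries, and the losses above both.

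By day 28 the acinar genes had regained most of their regions and held further ones that the untreated list lacked. In the same list endothelial genes had lost 87 of 176 regions (percentile 99.99). Whether the libraries differed in their share of acinar cells was not tested for these regions. Digestive enzyme genes lacked 29 of 281 regions (percentile 0) and had gained 72 (percentile 99.8), with 15 gained at Pnlip, 7 at Cpb1 and 7 at Gp2. Acinar transcription factor genes had gained 87 and lost 55 (percentiles 95.4 and 5.07), with 33 gained at Foxp1, 20 at Gata4 and 13 at Nr5a2, and none of them had lost a region at a gene end. Unfolded protein response genes had gained 51 and lost 26 (percentiles 97.6 and 1.94), of which 19 and 13 gained regions lay at Atf6 and Sel1l. Immediate-early and AP-1 genes had gained 114 and lost 65 (percentiles 99.98 and 1.15). Runx1 held 20 of these gained regions, Fosl2 13, Fos 9 and Klf6 9. Fibroblast and stellate genes had gained 52 and lost 20 (percentiles 99.5 and 0.57), so this other cell type's list moved with the AP-1 list at days 7 and 28.

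The inflammatory and NF-kB list had gained 63 and lost 62 regions at day 28 (percentiles 95.4 and 27.7), with 11 gained at Stat3, 10 at Nfkbiz and 6 at Osmr and 11 lost at Il4ra. Ductal and metaplasia genes had gained 74 and lost 68 (percentiles 98.2 and 25.7), with 10 gained at Cd44, 9 at Clu and 7 at Krt7, and 8 lost at Sox9. Endothelial genes had lost 87 of 176 regions (percentile 99.99) and gained 26 (percentile 10.3). Egfl7 had lost 16, Erg 16, Flt1 11 and Cdh5, which encodes VE-cadherin, 10 of 11, and 10 of the 14 genes had lost a region at a gene end. Tuft cell genes had gained 30 and lost 35 (percentiles 83.1 and 75.0), EGFR-MAPK genes 89 and 94 (percentiles 70.9 and 19.6), cell cycle genes 16 and 16 (percentiles 61.7 and 22.3), endocrine genes 27 and 23 (percentiles 92.5 and 62.0), leukocyte genes 8 and 15 (percentiles 27.6 and 85.4), erythroid genes 5 and 7 (percentiles 12.1 and 14.0), ubiquitous genes 23 and 10 (percentiles 96.4 and 2.39) and skeletal muscle genes 7 and 8 (percentiles 95.1 and 96.9).

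The strongest gained regions of day 28 lay 24254 bp from Rbm19 (15.6 fold), inside Scrt2 (15.04 fold, chromosome 2, 152092920 to 152093865), 26344 bp from the adrenomedullin gene Adm (14.8 fold, chromosome 7, 110655863 to 110656375), 27724 bp from Rc3h1 (13.9 fold) and inside Tiam1 (13.9 fold), followed by Pla2g2c, Wdr72, Rufy1, Sqstm1 and Cysltr2. All 10 were present at day 7 and 7 at day 1. The leading lost regions lay at P4ha2 (20.4 fold in the untreated list), Dip2a (19.9 fold), Zfp825 (18.3 fold) and Gm40035 (18.0 fold), followed by Ikzf2, Ugt1a1, Rec114, D430019H16Rik, Nln and Magi3. In total 30910 regions were gained, 23.7% of the list (23.52 to 23.98), and 37988 lost, 27.1% of the untreated regions (26.8 to 27.3), and the common enrichment floor gave 30033 and 38283. Unchanged simulated libraries gave at most 19216 gained and 11998 lost when drawn as a pair. Drawn with all 4 libraries, they gave 22633 to 43882 gained and at most 18911 lost, against 24415 and 33300 observed on the merged regions. The gains again lay above every pair draw but within the range of the draws with all 4 libraries, and the losses above both. Requiring a region to have a −log10 q of at least 5 where present and no peak at all where absent left 16485 gained and 24899 lost regions.

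**Figure D2:**
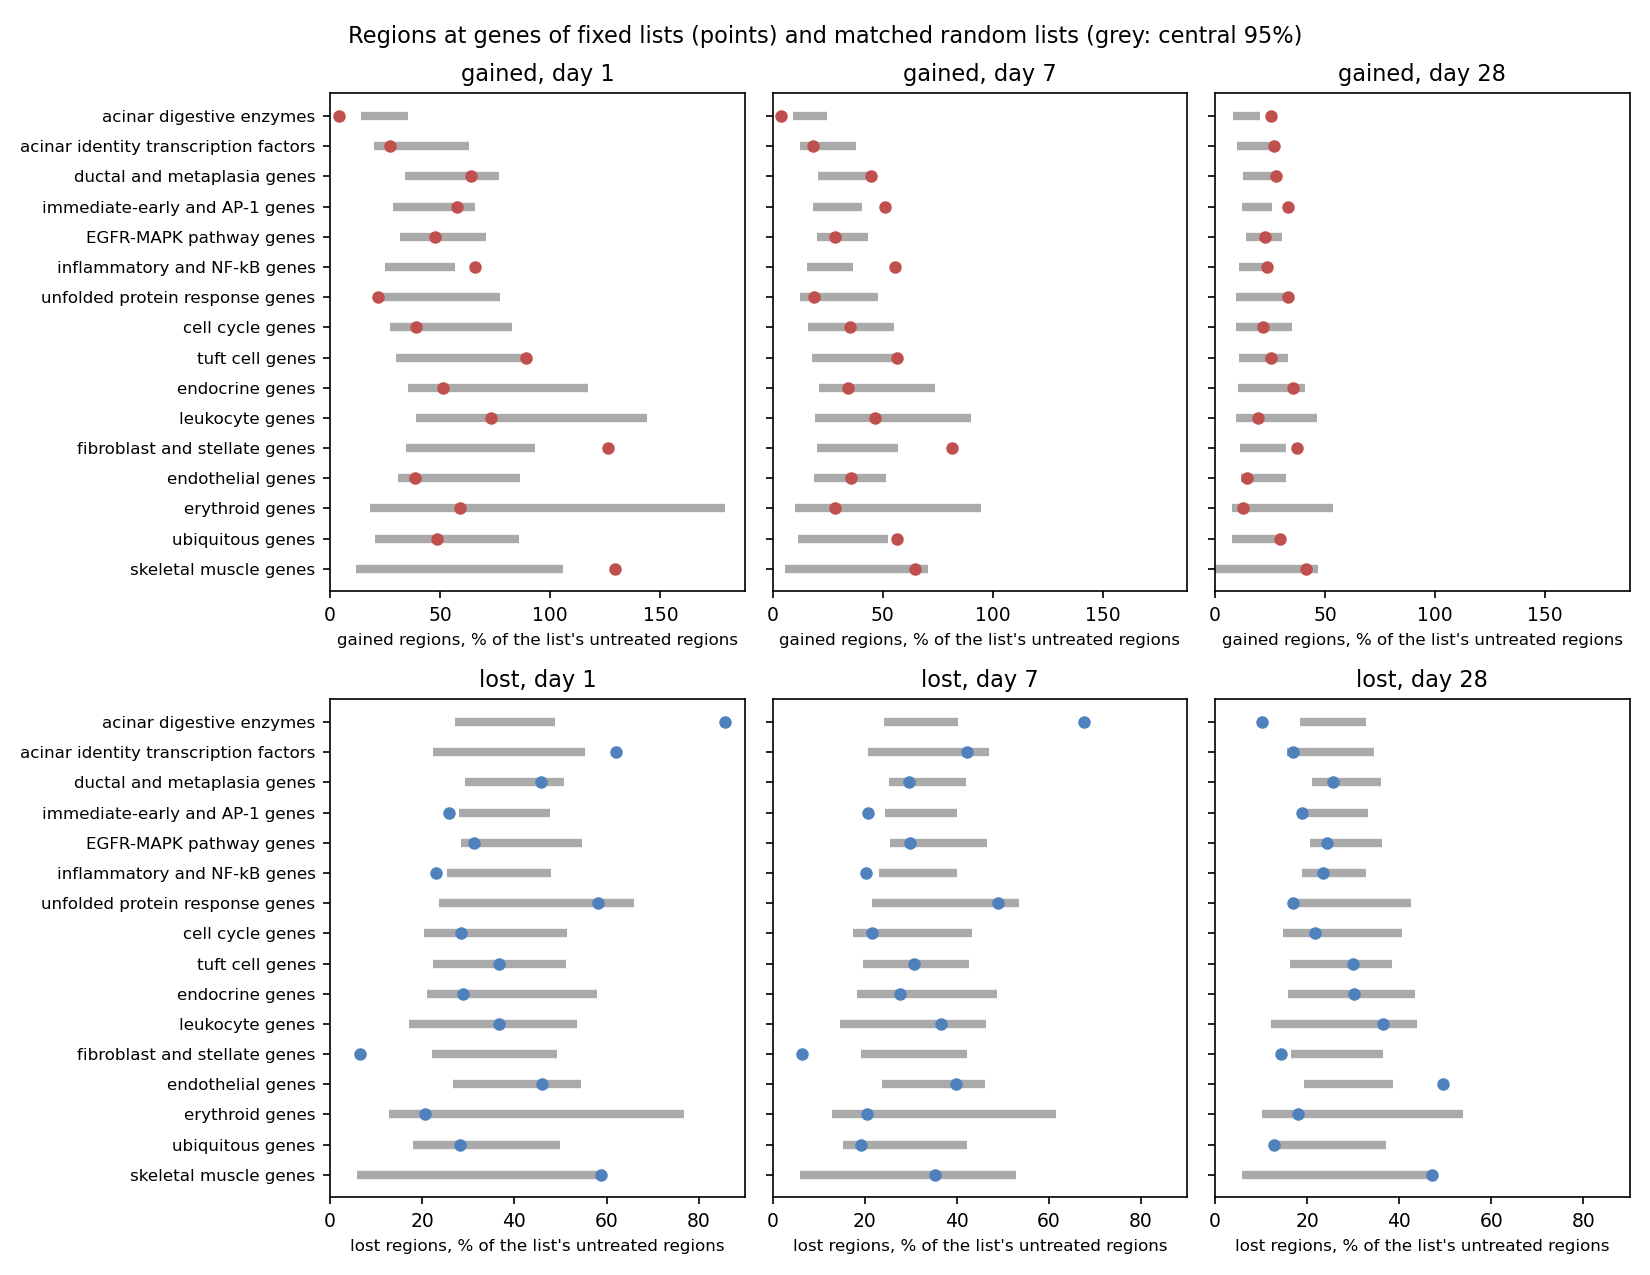
Gained (upper row) and lost (lower row) regions at the genes of 16 lists at days 1, 7 and 28, as a percentage of each list's untreated regions (horizontal axis), 1 library per time. Points show the list and grey bars the central 95% of 10000 matched random lists; the digestive enzyme genes lost 241 of 281 regions at day 1 and 29 at day 28, and the fibroblast list lay above its bar for gained regions at each time.

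The return of acinar regions was visible at a single locus, and new regions at another. In a window around Pnlip, at chromosome 19, 58650365 to 58701799, the lists held 23 peaks in untreated epithelium, 3 at day 1, 9 at day 7 and 33 at day 28, and the highest fold enrichments within each list were 42.0, 13.4, 7.52 and 43.7. In a window around Runx1, at chromosome 16, 92581466 to 92846074, they held 32, 52, 56 and 40 peaks.

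**Figure D3:**
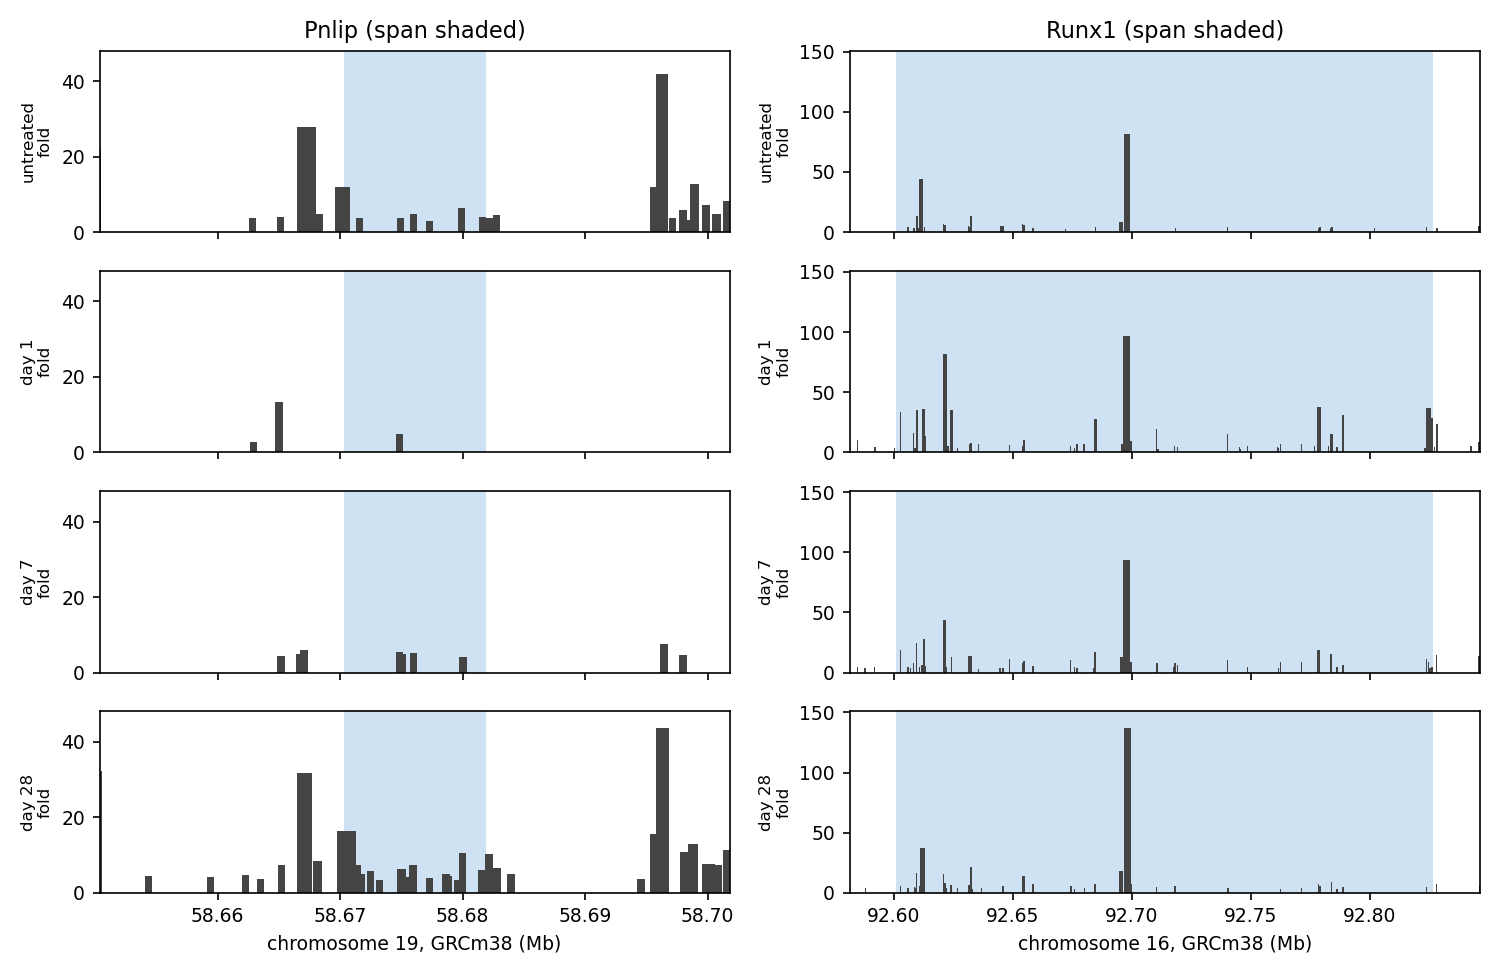
Peaks of the 4 lists around Pnlip (left) and Runx1 (right), with position in Mb on GRCm38 on the horizontal axis, the authors' fold enrichment on the vertical axis and the gene span shaded. Bars are peaks of 1 library per row; peaks at Pnlip number 23, 3, 9 and 33 from the untreated row to day 28, and those at Runx1 32, 52, 56 and 40.

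Most regions gained at day 1 were absent again at day 28. Of the 86230, 37.3% (37.0 to 37.6) overlapped a day 7 peak and 14.1% (13.9 to 14.4) a day 28 peak. Presence rose with the strength of the day 1 peak: in the bin of 17246 regions with fold enrichments from 8.82 to 81.3, 70.3% were present at day 7 and 23.4% at day 28, against 17.9% and 8.84% in the weakest bin. Of the 52526 regions lost at day 1, 72.3% (71.9 to 72.7) still had no peak at day 7 and 49.0% (48.6 to 49.4) none at day 28. These shares use the same untreated library as reference, which adds regions missed there by chance to every gain. On the merged regions of the 4 lists, where 12.9% of the day 1 gains were present at day 28, simulated unchanged libraries gave 33.3% to 64.7%. For the day 1 losses on the merged regions, 53.2% were absent at day 28, and 39.9% to 84.4% in the simulated libraries. Each simulated draw held at most 2389 day 1 losses against 47630 observed, so its share is no reference for how long the observed losses lasted. With another library in the role of the untreated reference, the 18 corresponding shares, each of regions in 1 list and absent from the reference that another list also held, ran from 8.66% to 73.7%. Of the day 1 regions absent at day 7, for example, 8.66% were present at day 28, and of the day 28 regions absent at day 1, 64.5% were present in the untreated list.

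**Figure D4:**
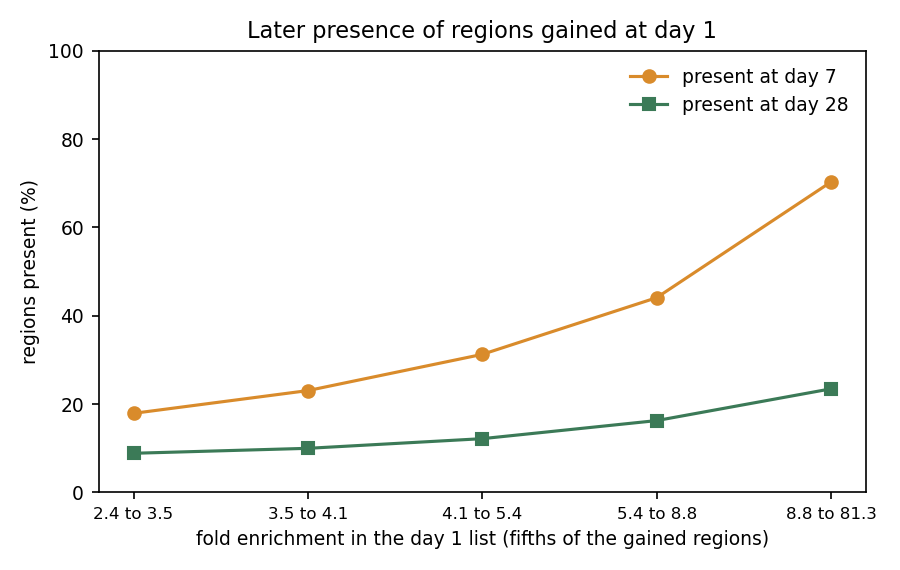
Percentage of regions gained at day 1 that overlapped a peak at day 7 (circles) or day 28 (squares), in 5 equal bins of the authors' day 1 fold enrichment, 1 library per time. The percentages run from 17.9 to 70.3 at day 7 and from 8.84 to 23.4 at day 28.

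Merging the 4 lists gave 223972 regions, of which 59902 were present in all 4 lists, 51456 at day 1 only, 23435 in the untreated list only and 20844 at days 1 and 7 only. With the common enrichment floor, which trimmed the day 1 list but not the untreated one, the order turned. There were then 23429 at day 1 only and 26061 in the untreated list only. Lists of equal length gave 34205 and 20681. A further 10681 were absent at day 1 alone. The pattern a lasting gain would leave, present at days 1, 7 and 28 and absent from the untreated list, held 8586 regions, of which 3024 reached a fold enrichment of 5 at day 28. Regions absent from the day 28 list alone numbered 5157. Simulated unchanged libraries gave 12314 to 35816 regions absent from the untreated list alone, more than were observed. Regions gained at both day 1 and day 28 numbered 10677. This was fewer than the 18976 that independent gains would give among the 106763 regions absent from the untreated list, and fewer than the 18287 to 43358 of simulated unchanged libraries. Regions lost at both numbered 25320, against 13532 if the losses were independent among the 117209 regions of the untreated list. With 1 untreated library the reference could not be divided, so part of the excess among losses may come from the shared reference. A merged region enters only if at least 1 list holds it, which by itself lowers the overlap of gains.

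Regions present at all later times and absent from the untreated list were frequent in the fibroblast list and in the immediate-early and AP-1 list, which includes Runx1 and Runx2. Counted as day 28 peaks they numbered 13314, or 43.1% of the day 28 gains. Immediate-early and AP-1 genes held 62 (percentile 100), of which 14 lay at Runx1, 8 at Fosl2, 6 at Fos and 4 at Runx2. Fibroblast and stellate genes held 45 (percentile 100), with 7 at Col1a2 and 5 at Col3a1. Inflammatory genes held 30 (percentile 98.4), with 5 each at Nfkbiz and Osmr, and ductal and metaplasia genes 34 (percentile 96.8), with 10 at Cd44. Digestive enzyme genes held 4 (percentile 0.92). The strongest such regions at day 28 were those named above at Scrt2, Adm, Rc3h1, Pla2g2c, Rufy1, Sqstm1 and Cysltr2. Regions inside Itsn1 (11.9 fold), near Tes (11.9 fold) and inside Kcnma1 (11.6 fold) came next. Among untreated regions lost at all later times, endothelial genes held 51 of 176 (percentile 99.6), the only list above its central range. Fibroblast genes held 2 of 140 (percentile 0), and the AP-1 and digestive enzyme lists also lay below their ranges.

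The whole lists ordered the libraries in the same way. The shared length divided by the joint length was 0.662 for untreated and day 28, 0.584 for days 7 and 28, 0.577 for days 1 and 7, 0.535 for untreated and day 7, 0.423 for days 1 and 28 and 0.392 for untreated and day 1. With the common enrichment floor days 1 and 7 (0.591) stood above days 7 and 28 (0.587). Gained and lost regions alike lay away from gene ends. Of the regions gained at day 1, 4.81% were within 1 kb of an annotated gene end (4.67 to 4.96), and of those lost 6.68% (6.47 to 6.90). Among those shared with the untreated list the share was 19.4% (19.1 to 19.7). Inside a gene lay 54.4% of the gained, 61.3% of the lost and 59.6% of the shared regions. At day 28 the gained, lost and shared regions lay near gene ends in 6.59%, 7.85% and 16.8%, and inside a gene in 60.1%, 60.1% and 60.2%. Gained and lost regions were also narrower than shared ones, with median widths at day 1 of 282 and 219 against 623 bp. In the day 1 list the gained regions were weaker too, with a median fold of 4.57 against 12.0 for shared ones. The regions lost at day 1 had a median fold of 3.95 in the untreated list, whose own median was 4.78. Location was not compared at equal strength.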

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

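Gene lists whose balance of gained and lost regions took opposite signs at day 1 and day 28, and reached 10% of the list's untreated regions at both times, were singled out; with 1 library per time these differences were not tested. At the digestive enzyme genes gained minus lost regions came to -230 at day 1 and 43 at day 28. At the unfolded protein response genes the balance was -56 at day 1 and 25 at day 28. Leukocyte genes had a balance of 15 at day 1 and -7 at day 28. Opposite signs below that limit occurred in the acinar transcription factor list (-113 and 32), the EGFR-MAPK list (63 and -5), the tuft cell list (61 and -5), the erythroid list (15 and -2), the skeletal muscle list (12 and -1) and the added stromal transcription factor list (105 and -8). Over all regions gains also outnumbered losses at day 1 (86230 and 52526), and losses outnumbered gains at day 28 (37988 and 30910). Lists that turned from plus to minus therefore followed the balance over all regions. The leukocyte totals lay within the central range of their random lists at both times. The signs were opposite in all 7 settings run for the gene lists at the digestive enzyme, unfolded protein response and acinar transcription factor genes. With the common enrichment floor the day 1 balance was -3 at the leukocyte genes and -58 at the EGFR-MAPK genes, so neither had opposite signs there. Opposite signs held in 6 of the 7 settings for the leukocyte genes and in 2 for the EGFR-MAPK genes. The remaining lists named here lost opposite signs in at least 1 setting.

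The Y chromosome, which the main comparisons left out, held 11 peaks at day 1 against 9 in the untreated list, 7 at day 7 and 6 at day 28. Each list also held 1 peak at Xist, with fold enrichments of 10.9, 3.78, 6.98 and 11.4 from untreated to day 28. Regions on X made up 1.22% of the untreated list and 1.76%, 1.59% and 1.59% of those of days 1, 7 and 28. The reason for the lower untreated share was not tested. The sex of the mice is not given in the sources used here.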

How the results depend on the processing

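The settings with a fold of at least 3, thinning, a common enrichment floor and a day 28 fold of at least 5 were chosen after the data had been seen. The percentages of day 1 gains present at day 28, of day 1 gains present at day 7, of day 1 losses absent at day 28 and of day 1 losses absent at day 7 were, in this order, 10.9, 31.3, 56.4 and 74.5 with reciprocal overlap, 9.75, 34.2, 41.3 and 67.6 with the margin, 17.4, 41.8, 43.6 and 70.1 with lists of equal length, 13.3, 38.6, 38.0 and 67.9 with the minimum width, 15.1, 39.5, 46.8 and 70.3 with a fold of at least 3, 17.0, 41.9, 44.0 and 67.5 after thinning, and 17.6, 47.2, 46.1 and 68.3 with the common floor. The stricter q gave 11.7, 36.4 and 47.1 for the first 3, and the fourth stayed within its interval. Reciprocal overlap, which counts peaks sharing less than 50% of either as separate, raised gained regions to 82898 at day 7 and 51338 at day 28 and lost regions to 96119, 77847 and 61475 at days 1, 7 and 28. The minimum width lowered lost regions to 33146, 26375 and 19988 and day 28 gains to 20118. Day 28 gains were 20263 with the stricter q and 16485 with the margin, and day 28 losses 24899 with the margin. The common floor gave 46643 day 1 gains, and 3024 of the regions absent from the untreated list alone had a day 28 fold of at least 5. Removing regions can lower or raise these counts. The common floor kept all 140286 untreated regions and 110780 at day 1, so its rise in day 1 losses to 63089 follows from its construction; other causes were not tested. The other counts of regions gained and lost stayed within 1.5 times their main values. Counts at gene lists and of presence patterns moved by more than that in 28 of the values with links within 10 kb, 31 with the stricter q, 20 with the common floor, 7 with equal list length and 5 after thinning. Over the settings run for the gene lists, the percentile of regions lost at digestive enzyme genes at day 1 was 100 throughout, and that of regions gained at fibroblast genes ran from 99.9 to 100. Others moved more: at day 28 the percentile of gained regions ran from 88.7 to 99.99 for unfolded protein response, 56.7 to 96.6 for ubiquitous, 92.3 to 99.3 for acinar transcription factor and 91.1 to 96.0 for inflammatory genes, at day 7 from 90.8 to 99.05 for ubiquitous genes, and at day 1 from 74.6 to 98.7 for ductal and metaplasia genes and from 0.005 to 78.8 for endocrine genes. The percentile of regions lost at day 28 ran from 1.225 to 10.3 for unfolded protein response and from 1.28 to 30.3 for ubiquitous genes. The alternatives for motif content were not run, because no genome sequence was at hand. No paired analysis was possible because each group held 1 library. Depth limits the lists of days 7 and 28 most, with about the same background of 2.72 and 2.52.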

Other observations

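Genes with the most regions were ranked over the whole annotation without regard to the lists, a ranking made after the data had been seen, and the tests on regions lost at day 1 and on regions absent from the day 28 list alone were likewise chosen after their results were seen. At day 1 the genes with the most gained regions included Slit3 with 133, Rbms3 with 122 and Tnc, which encodes the matrix protein tenascin C, with 86 against 10 in the untreated list. Long genes collect more regions, and the territory was 668 kb for Slit3 but 188 kb for Tnc. Gfpt2, with a territory of 88 kb and 14 untreated regions, had gained 51 at day 7. At day 28 Snd1 had gained 85 regions, Fndc3b 55 and Chka 32 in a territory of 62 kb. Of the regions absent from the untreated list and present at each later time, 18 lay at the homeobox gene Hoxb3 in a territory of 40 kb. Gse1 led the lost regions at each time, with 112 at day 1, 101 at day 7 and 68 at day 28 of 197.

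The many regions gained and lost at day 1 may partly reflect differences in depth, overall enrichment and counting error. A simulation of unchanged libraries, with its prediction written beforehand, reached 82290 gained regions on the merged regions against 82977 observed under the assumption that gave the most. The other assumptions reached 55414 and 67387, and pairs of libraries at most 59603 against 86230. Under the assumption that reached 82290, at least 41.1% of the day 1 gains were present at day 28, against 12.9% observed. Matching the number of gains thus did not match how many of them recurred. Each region's simulated accessibility was averaged over the observed lists, so any real gains entered the simulation too. The draws therefore cannot tell what part of the gains these technical differences produced, and the simulated number depends on the assumption. For the losses the tables argue against this explanation: the day 28 list, shallower and less enriched than that of day 1, lacked 37988 untreated regions against 52526 at day 1, where these differences would leave at least as many missing at day 28. Variation between libraries or animals unrelated to caerulein cannot be told apart from the treatment, because there was 1 untreated library. The injury itself remains open as an explanation, untested beyond these values.

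The 8586 regions present at days 1, 7 and 28 and absent from the untreated list could arise from depth, overall enrichment and counting error. Simulated unchanged libraries gave up to 35816 such regions and in no draw fewer than 12314, so their number alone is no evidence of a lasting gain. Of those with a day 28 fold of at least 5, a cut chosen after the data had been seen, 3024 were observed. The simulations gave at most 1208, 1606 and 2666 with the absent level at background, halfway and the floor. The observed number lay above every draw, but the size of the excess depends on the assumption, and no conclusion is drawn from it. Each list also misses regions that the others hold, with 5157 absent from the day 28 list alone, 10681 from the day 1 list alone and 1697 from the day 7 list alone. These lie on both sides of 8586, so this remains undecided. A peculiarity of the untreated library cannot be told apart from a lasting effect of the inflammation with 1 such library.

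The regions gained at fibroblast and stellate genes at day 1 could come from stromal cells left in the preparation, although the epithelial cells were purified. All 15 of the stromal transcription factor genes and 15 of the 16 fibroblast genes already had regions in the untreated list. In the test with the stromal transcription factor list, its 132 gained regions lay at percentile 87.1, short of the 95 set beforehand and above 50, while its 27 lost regions of 175 lay at percentile 0; with links within 10 kb and other settings the first percentile ran from 69.2 to 99.8. Stromal cells and a change within epithelial cells therefore cannot be told apart here. A lower share of acinar cells was predicted to raise gained regions at leukocyte, endothelial and endocrine genes above percentile 95 at day 1. They lay at percentiles 39.7, 12.1 and 17.4, so the prediction was not met. This does not argue against a lower share, because a rise common to other cell types could also lift the matched random lists. Cell types also need not rise alike, so a lower acinar share stays open. At days 7 and 28 the stromal list had gained 97 and 47 regions (percentiles 97.4 and 85.2) and lost 29 and 55 (percentiles 0.045 and 76.7), and 30 of its regions were absent from the untreated list and present at each later time (percentile 98.3).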
